A study of Mus musculus with 2 samples.

How the data were processed

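MicroRNA sequencing measured the short RNAs of mouse hippocampus, labelled as layer of hippocampus, in 2 libraries. The labels give these as biological replicates 1 and 2 of a single group of male 5xFAD mice aged 8 months. The labels name total RNA as the molecule and a size range below 30 for the sequenced RNA. A separate tag on both samples gives sex as not collected. The samples are separate biosamples under one donor record, and nothing in the labels says that they came from separate animals, so their spread may be technical. The labels link the libraries to different documents on adapter trimming, so trimming and replicate number cannot be separated.

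The authors deposited 1 table of counts per library, with reads counted per annotated microRNA gene on assembly mm10 (GRCm38) with GENCODE M21, per the readme file beside each table. The aligner and the counting program are not given in the sources used here. Each table lists 2202 genes and 4 summary lines for reads that were unmapped, mapped to several places, fell in no gene or were ambiguous. Counts are given on either strand, on the sense strand and on the opposite strand. The values are whole numbers with no normalization. A count belongs to a hairpin gene, so the mature arms of a hairpin are not separated. All 2202 gene IDs matched the annotation, which supplied symbols, positions and overlaps with other genes, and 1174 of them carry a Mir symbol.

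Sense-strand counts were used throughout, and the summary lines stayed out of library totals and tests. Summary lines held 59.9% of the reads in replicate 1 and 58.5% in replicate 2. Reads that mapped to several places made up 44.65% and 44.69%, unmapped reads 12.43% and 10.68%, and reads outside any listed gene 2.819% and 3.132%. Counts scaled to a common library size (CPM, the usual unit of counts relative to the library total) were computed from the sense counts at all listed genes, 4326551 in replicate 1 and 4465231 in replicate 2. At that depth 1 count equals 0.231 CPM in replicate 1 and 0.224 CPM in replicate 2. A count of 0 allows a level of up to 3 uniquely assigned counts, or 0.693 and 0.672 CPM, and sets no limit where reads map to several places. The labels name no molecular identifiers, and amplified reads are then not independent molecules, so floors and count tests cover counting error only.

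With 1 group of 2 libraries there was no contrast between conditions, and non-transgenic samples were not analysed here. The spread between the libraries was estimated as the common dispersion in edgeR 4.0.16 under R 4.3.3 with TMM scaling, over genes with 10 or more counts summed over both libraries. Its interval over genes came from 100 bootstrap resamples of genes. A chi-square test over the same genes asked whether the libraries differed by more than sampling noise. Each gene was compared between the libraries with a two-sided exact binomial test given the totals, with Benjamini-Hochberg adjustment at 0.05. This test compares the libraries and not conditions. Log2 ratios are replicate 2 over replicate 1 of CPM with a pseudocount of 0.5 counts.

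Fixed before the data were examined were 15 gene lists with 151 stems of gene names. They covered brain cell types, other tissues, let-7, the Dlk1-Dio3 cluster and the miR-17-92 family, which includes Mir92b. The others covered genes linked to App and Bace1, stress and inflammation, and the repeated genes of the Sfmbt2 type. A stem took the matching symbol with an optional copy number. For 3 stem entries the annotation uses an older symbol, Mir146 for miR-146a and Mir18 for miR-18a. Each list's median was placed among 10000 random lists of the same size. For levels these were drawn from genes with a Mir symbol, and for ratios they were matched on mean expression. The percentiles describe these libraries and are not p-values.

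The genes named were also set by rule. They are the 20 with the highest mean CPM, the 4 highest members of each list at 1 CPM or more in both libraries, and the 10 with the largest log2 ratio in size among those with a mean of 100 CPM or more. That gave 71 genes. Any other gene named was chosen after its values were seen. Genes that carry a copy number or lie antisense to another microRNA gene are given as uncertain, because identical mature sequences share reads and the strand handling of the counting program is known only from its columns. Genes without an annotated antisense partner had 159 and 117 opposite-strand counts in replicates 1 and 2. These low values argue against reads counted on the wrong strand.

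Alternatives were the either-strand counts, totals or DESeq2 1.42.0 size factors in place of TMM and the reverse, other filters on low counts, a pseudocount of 5 counts, lists without copy-numbered genes, other denominators, other detection limits and each replicate alone. A correction for GC content, lists without the older-name matches and the copy comparison without the repeat list were added after seeing the data. The dispersion estimate was tested on simulated counts over 511 genes, and returned 0.0975, 0.304 and 0.523 where 0.1, 0.3 and 0.5 had been put in. In simulated libraries with sampling noise alone, the exact binomial test called 2.57% of 311 genes with equal levels, and 56%, 52%, 74% and 96% of 50 genes each with a fold of 1.25, 1.5, 2 and 4. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining computation.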

Results

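The series profiled microRNAs in tissue labelled layer of hippocampus from 5xFAD mice. This transgenic line carries familial Alzheimer's disease mutations in human APP and PSEN1 and forms amyloid deposits. The 2 libraries are replicates of one group, male and 8 months old. They held 10788970 reads in replicate 1 and 10760431 in replicate 2, of which 4326551 (40.1%) and 4465231 (41.5%) were counted in sense at a microRNA gene. The design allows a profile with its replicate spread, and no comparison between conditions.

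A small number of microRNA genes held most of the counts. Ranked within each library, the most abundant gene (Mirlet7i in replicate 1, Mir139 in replicate 2) took 14.8% ± 5.01 (SD, n = 2) of the counts, the top 10 took 61.9% ± 2.11 and the top 20 took 74.3% ± 1.12. Of the 2202 listed genes, 473 with a Mir symbol and 11 with a provisional Gm symbol reached 1 CPM in both libraries, as did 3 with other names (Snord43, n-TSaga9 and mmu-mir-3535, named after their values were seen), 301 reached 10 CPM, 181 reached 100 CPM and 83 reached 1000 CPM. Of all reads, including those not assigned to a gene, the top 10 held 25.3%. No count fell in 1441 genes in either library, which allows up to 0.693 CPM of uniquely assigned reads in replicate 1 and 0.672 CPM in replicate 2 and sets no limit on genes whose reads map to several places. By overlap with other annotated genes on the same strand, genes in introns held 48.3% ± 1.95 (SD, n = 2) of the counts and genes in exons 35.5% ± 0.997. Genes without such an overlap held 16.3% ± 0.957. Overlaps on the opposite strand were not considered, so these genes need not lie between annotated genes.

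Reads that mapped to several places outnumbered those assigned to genes, at 1.11 and 1.08 times in replicates 1 and 2, so ranks hold only among assigned reads. By mean CPM of assigned reads, Mir139 ranked highest, at 146962 ± 51120 CPM (SD, n = 2). It lies in an intron of the phosphodiesterase gene Pde2a on chromosome 7 (101475376 to 101475443, GRCm38). Next came let-7 genes, whose products are abundant in differentiated tissues. Mirlet7b stood at 96634 ± 23888 CPM on chromosome 15 (85707319 to 85707403, an exon of Lncppara), Mirlet7i at 94145 ± 25586 CPM on chromosome 10 (122985640 to 122985724) and Mirlet7g at 76546 ± 31512 CPM in an intron of Wdr82 on chromosome 9 (106178840 to 106178927). Given these SDs, the order of the 4 genes was not resolved. Mir139 led in replicate 2 with 183110 CPM, and Mirlet7i led in replicate 1 with 112237 CPM against 110815 CPM for Mir139. Mir127 followed at 50960 ± 3690 CPM, then Mirlet7d at 42307 ± 5548 CPM, Mir744 at 35403 ± 8497 CPM, Mirlet7e at 29479 ± 3464 CPM, Mir23b at 27879 ± 1082 CPM and Mir99a at 15835 ± 2824 CPM. Mirlet7e is annotated antisense to Gm25927 and is marked uncertain by rule. Gm25927 had 0 sense counts in both libraries, and its opposite-strand counts (116945 and 142571) equal the sense counts of Mirlet7e. The rest of the top 20 were Mir125a, Mir770, Mir23a, Mir652, Mir191, Mir221, Mir324, Mir149, Mir132 and Mir99b, and the lowest of these had a mean of 9723 CPM.

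The let-7 list as a whole held 34.6% ± 3.65 (SD, n = 2) of the counts, with all 12 members at 1 CPM or more. Of these, 6 carry copy numbers (let-7a, let-7c and let-7f), and without them the list held 34.1%. Reads that map to several places were not assigned, so the counts set no limit on the levels of these 3. The median level of the let-7 list stood at percentile 100 among random lists drawn from all Mir genes, detected or not. So did those of the neuronal and Dlk1-Dio3 lists. Mir98, a member in an intron of the ubiquitin ligase gene Huwe1 on the X chromosome, had 1717 ± 1040 CPM.

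**Figure D1:**
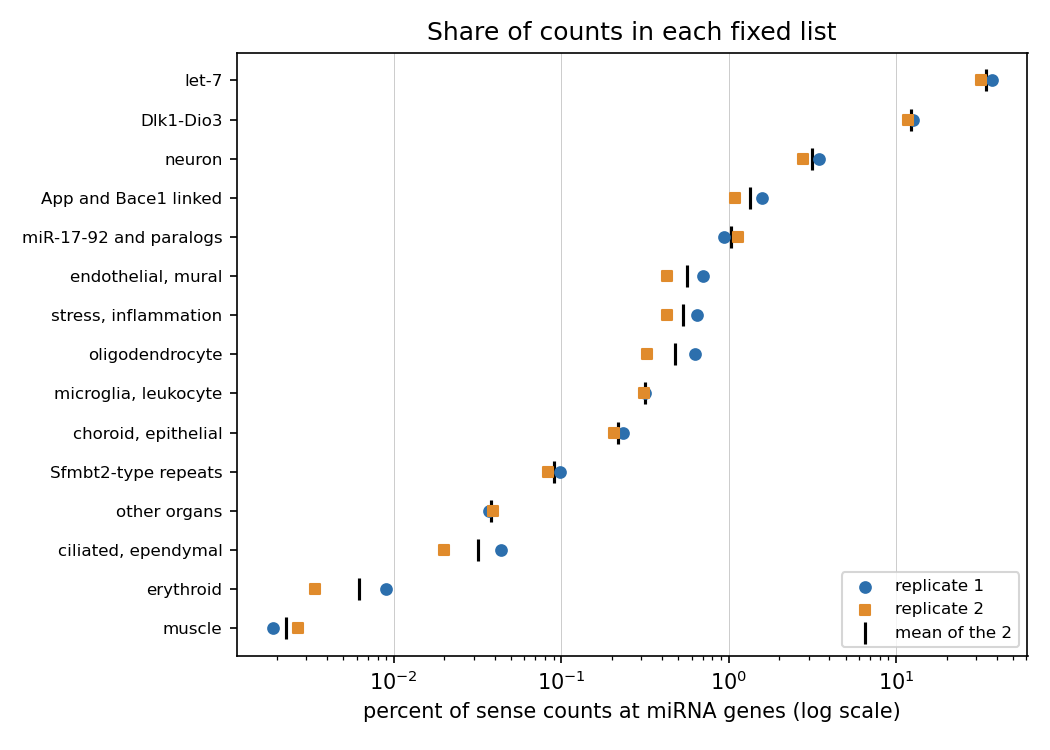
Percent of sense counts at microRNA genes held by each of the 15 fixed lists, on a log axis, with circles for replicate 1, squares for replicate 2 and a bar for their mean. The let-7 list held 34.6% and the Dlk1-Dio3 list 12.2% on average, and the muscle list held 0.00228%.

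Neuronal microRNA genes held 3.13% ± 0.499 (SD, n = 2) of the counts, and 18 of the 23 listed genes reached 1 CPM in both libraries. Mir132, which neuronal activity induces, had 11070 ± 3975 CPM (chromosome 11, 75173682 to 75173747). Mir128-1 had 5244 ± 1682 CPM in an intron of R3hdm1, Mir138-1 had 3361 ± 1629 CPM and Mir138-2 had 3162 ± 800.8 CPM. These last 3 carry copy numbers, so their levels are uncertain. In all, 16 of the 23 listed genes carry one, and without them the list held 1.57%. The copies of miR-124, a microRNA of neurons, were near the floor. Mir124a-1 had 5 and 2 counts in replicates 1 and 2, Mir124a-2 had 2 and 1 and Mir124a-3 had 4 and 5. Reads that map to several places were not assigned to genes in these tables, so the counts set no limit on the level of mature miR-124.

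Glial, vascular and blood cell lists were smaller. The oligodendrocyte list held 0.478% ± 0.214 (SD, n = 2), mostly through Mir219a-2 at 3168 ± 1955 CPM and Mir338 at 1607 ± 183.5 CPM, whose products promote oligodendrocyte differentiation. Mir219a-1 had 9.00 ± 1.33 CPM. All 3 lie antisense to another microRNA gene. Either-strand counting leaves out reads at such antisense pairs, so none of the list's counts was left there. Without copy-numbered genes the list held 0.161%. The microglia and leukocyte list held 0.315% ± 0.00469, with Mir150 at 1590 ± 279.2 CPM, Mir146 (miR-146a) at 1289 ± 332.8 CPM, Mir155 at 247.8 ± 4.61 CPM and Mir142 at 13.4 ± 1.91 CPM. Mir142 is marked uncertain for its antisense gene Mir142b, which had 0 sense counts in both libraries. Without Mir146 the list held 0.186%. The endothelial and mural list held 0.567% ± 0.198, led by the endothelial Mir126a in Egfl7 at 3789 ± 1760 CPM, antisense to Mir126b, with Mir143 at 1702 ± 249.7 CPM and Mir145a at 176.4 ± 32.1 CPM from smooth muscle and pericytes. The erythroid list held 0.00622% ± 0.00398, with Mir451a at 53.2 ± 39.5 CPM and Mir486 at 7.95 ± 0.788 CPM, both with an antisense partner. With either-strand counting the endothelial list held 0.200% and the erythroid list 0.00011%. Median levels of these lists stood at percentile 88.7 for oligodendrocytes, 90.5 for microglia and leukocytes, 97.9 for endothelial and mural genes and 72.8 for erythroid genes.

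Markers of epithelia and other organs held small shares. Their median levels stood at percentile 99.5 among random lists for the choroid and epithelial list, 92.1 for the ciliated list, 77.1 for other organs and 13.1 for muscle. Of the 1174 Mir genes behind the random lists, 473 reached 1 CPM in both libraries. A high percentile is therefore no evidence by itself that the tissue expresses a list. The choroid and epithelial list held 0.219% ± 0.0188 (SD, n = 2), of which Mir204 in an intron of Trpm3 had 1565 ± 15.3 CPM, Mir211 in an intron of Trpm1 150.5 ± 11.8 CPM, Mir200b 131.7 ± 44.7 CPM and Mir429 120.3 ± 57.4 CPM. The ciliated and ependymal list held 0.0316% ± 0.0167, with Mir34c at 257 ± 172.2 CPM, Mir34b at 36.7 ± 12.7 CPM and Mir449a at 22.5 ± 7.10 CPM. The list of other organs held 0.0380% ± 0.00148. It contained Mir375 of endocrine cells at 314.9 ± 24.7 CPM, the liver gene Mir122 at 37.8 ± 5.99 CPM, Mir203 at 23.7 ± 2.14 CPM and Mir205 at 1.93 ± 0.118 CPM. The muscle list held 0.00228% ± 0.000544, with Mir206 at 20.3 ± 4.86 CPM and Mir499 at 2.38 ± 0.751 CPM.

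Genes described in the literature as acting on App or Bace1, the gene of beta-secretase, held 1.33% ± 0.352 (SD, n = 2), and 12 of 17 reached 1 CPM in both libraries. Mir29a had 8544 ± 708.5 CPM, Mir107 3090 ± 2863 CPM, Mir195a 511.7 ± 231 CPM and Mir29c 284.4 ± 154.8 CPM. Mir107 and Mir29c each share 18 bases with 2 other microRNA genes, so their levels are uncertain. The stress and inflammation list held 0.537% ± 0.157, with Mir34a at 2106 ± 1353 CPM and with Mir125b-2 and Mir125b-1, which carry copy numbers, at 747.6 ± 7.67 and 733.9 ± 129.5 CPM. Mir146 is also a member. The miR-17-92 family held 1.04% ± 0.144, with Mir92b at 7372 ± 1291 CPM, Mir93 at 1590 ± 96.6 CPM, the copy-numbered Mir92-1 at 537.5 ± 142.8 CPM and Mir17 at 387.6 ± 85.0 CPM. Mir92b made up most of that share and lies on chromosome 3, while Mir92-1 and Mir17 lie together on chromosome 14. The share is therefore not that of the miR-17-92 cluster. Among the repeated genes of the Sfmbt2 type, 9 of 81 reached 1 CPM in both libraries and the list held 0.0906% ± 0.0109. Mir467d had 497.3 ± 89.1 CPM, Mir669c 163.1 ± 21.1 CPM, Mir467c 74.4 ± 15.01 CPM and Mir467e 72.8 ± 20.9 CPM, all in an intron of Sfmbt2. They carry no copy number, but share 18 bases with 16, 86, 30 and 17 other microRNA genes in that order, so their levels are uncertain too. Median levels stood at percentile 99.97 for the App and Bace1 list, 99.9 for stress and inflammation, 99.2 for miR-17-92 and 1.49 for the repeated genes.

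The imprinted Dlk1-Dio3 cluster, a maternally expressed run of microRNA genes, held 12.2% ± 0.654 (SD, n = 2) of the counts. On chromosome 12, 48 of its 55 listed genes reached 1 CPM in both libraries over 184.3 kb (109563692 to 109747960), and 1 listed gene lies on another chromosome. Levels within the cluster ranged from 5.58 to 50960 CPM, a span of 9132-fold. Mir127 was highest (109592846 to 109592915), ahead of Mir770 in an exon of Meg3 at 15146 ± 2772 CPM (109563692 to 109563785), Mir382 in an exon of Mirg at 8347 ± 2424 CPM and Mir433 at 8188 ± 924 CPM. The SD of log2 CPM over the 48 genes was 2.96, and the SD of their log2 ratios between the libraries was 0.51.

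**Figure D2:**
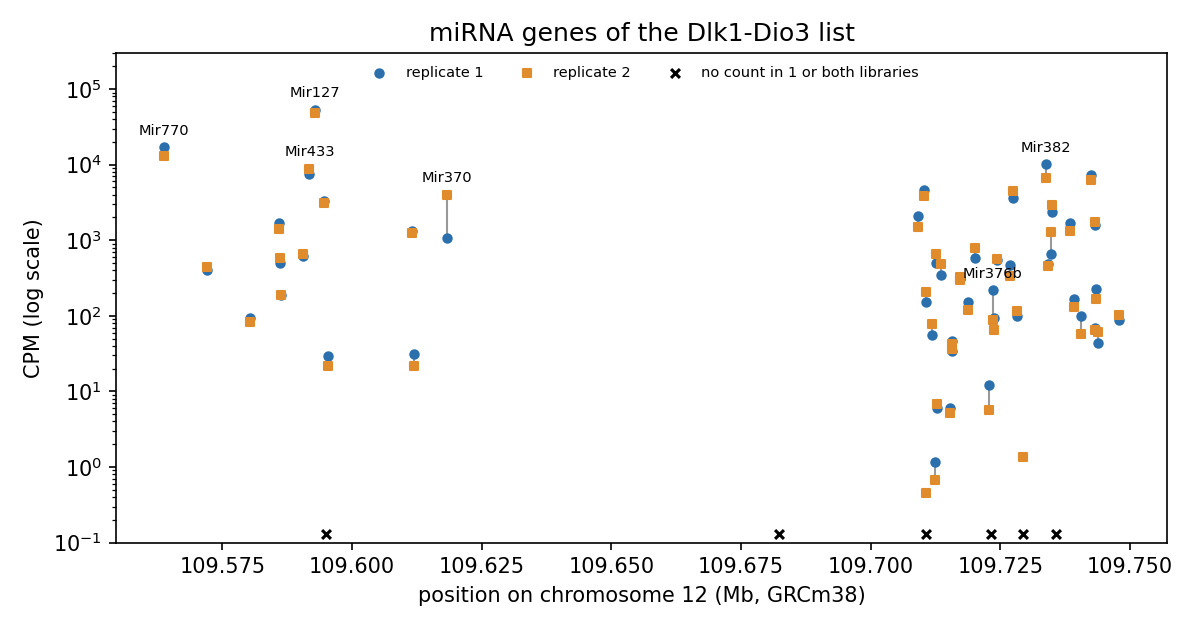
CPM on a log axis of the Dlk1-Dio3 list genes by position on chromosome 12 (Mb, GRCm38), with circles for replicate 1, squares for replicate 2 and crosses for genes with no count in 1 or both libraries. Levels spread from 5.58 to 50960 CPM among the 48 genes at 1 CPM or more, while 39 of these differed by less than 0.5 in log2 ratio between the libraries.

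The libraries ranked the genes alike and differed in many levels. Across the tested genes (10 or more counts in total), which are not independent replicates, Pearson's r of log2 CPM was 0.98 and Spearman's rho 0.973. The common dispersion corresponded to a biological coefficient of variation of 0.3 (0.2996, interval over genes 0.265 to 0.332). The chi-square over genes was 619.9 per degree of freedom, so the libraries differed by far more than sampling noise. This separates them from duplicate copies of 1 library, but not from 2 preparations of one sample. The exact binomial test gave 241 genes (47.2%) that differed between the libraries and 270 that did not pass. That share depended on the filter for low counts, at 73.4% (226 of 308) for a mean of 10 CPM or more and 30.6% (233 of 761) for 1 or more counts. The main filter gave 94 genes at a ratio of 1.5 or more and 49 at a ratio of 2 or more. Of the 49, 20 were higher and 29 lower in replicate 2. The median log2 ratio was -0.0047. The median coefficient of variation was 13.3% for the 89 genes at a mean of 1000 CPM or more, 17.1% from 100 to 1000 CPM, 19.4% from 10 to 100 CPM and 26.2% from 1 to 10 CPM.

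Of the 20 most abundant genes, 19 differed between the libraries by the exact binomial test, 6 of them higher and 13 lower in replicate 2, and 5 by 1.5-fold or more. The exception was Mir191, with 11939 and 12032 CPM (adjusted p = 0.323, exact binomial test) and an antisense partner, Gm24083. Among genes at a mean of 100 CPM or more, Mir31 had the largest ratio, 864 CPM in replicate 1 and 73.7 CPM in replicate 2, an 11.7-fold difference (chromosome 4, 88910557 to 88910662). Mir107 in an intron of Pank1 had 5115 and 1066 CPM in replicates 1 and 2, and Mir183 had 196.5 and 41.2 CPM. Mir298, Mir34c, Mir34a, Mir219a-2, Mir98 and Mir376b were lower in replicate 2 by 2.47-fold to 3.37-fold. Mir107, Mir219a-2 and Mir376b each share 18 bases with 2 other microRNA genes, so their levels are uncertain. Mir370, in an intron of Rian in the Dlk1-Dio3 cluster, was the only one of these 10 that was higher in replicate 2, at 3999 CPM against 1067 CPM.

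**Figure D3:**
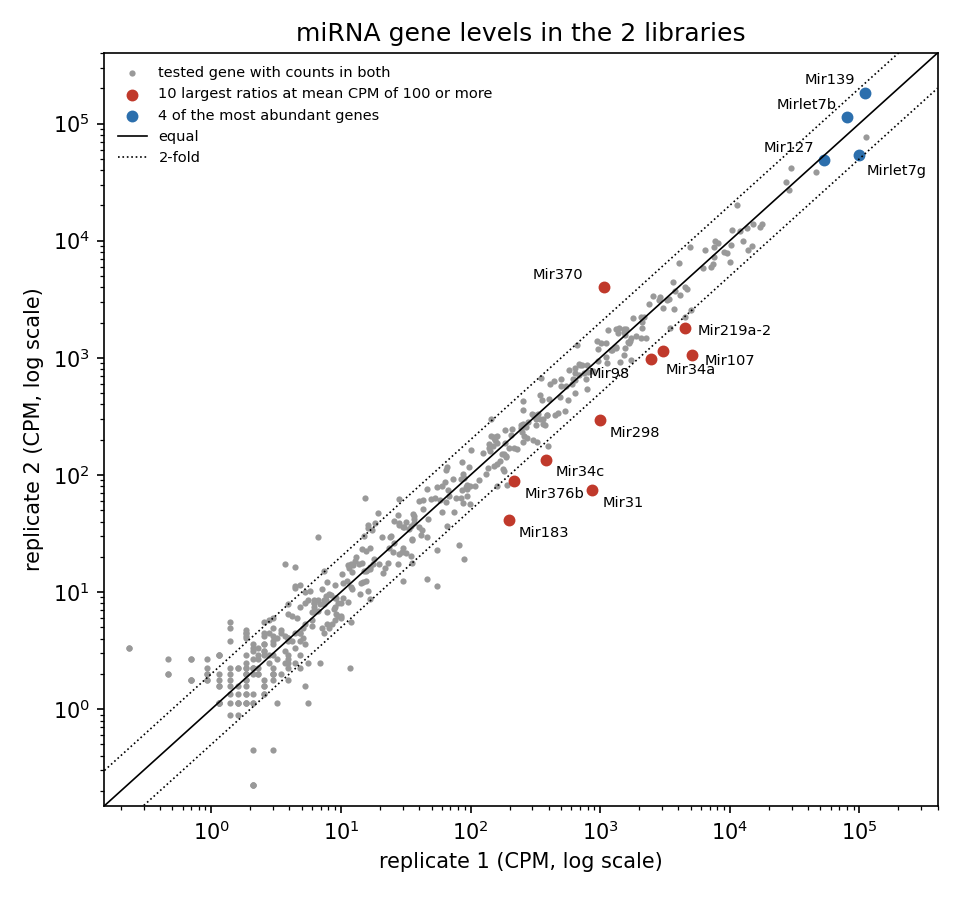
CPM of each tested gene with counts in both libraries, replicate 1 against replicate 2 on log axes, with a solid line for equal levels and dotted lines for a 2-fold difference. Red points are the 10 genes with the largest ratios at a mean of 100 CPM or more, 9 of them below the line and Mir370 above it, and blue points are 4 of the most abundant genes.

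Choroid and epithelial genes had a median log2 ratio between the libraries of -1.01 (percentile 0.015 among random lists of like expression). Most members are not independent, since Mir183 lies near Mir182, Mir200c near Mir141, and Mir200a, Mir200b and Mir429 lie together. The random lists drew genes singly, so the percentile may overstate how unusual the list is. Of 9 tested members, 6 were lower and 1 was higher in replicate 2, and 7 differed both over all genes and adjusted over the list alone. Mir183 and Mir429 were lower by 2.25 and 1.01 on the log2 scale, and Mir200b was higher by 0.71. The choroid plexus genes Mir204 and Mir211 gave log2 ratios of 0.02 and 0.16 (adjusted p = 0.554 and 0.0868, exact binomial test).

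The other lists stayed within the central range of random lists. The medians were -0.19 for neurons (6 higher, 9 lower, 16 of 18 adjusted over the list alone), -0.30 for oligodendrocytes (0 higher, 2 lower, 2 of 3 alone), 0.20 for microglia and leukocytes (2 higher, 1 lower, 3 of 6 alone) and -0.30 for endothelial and mural genes (1 higher, 2 lower, 3 of 3 alone). Erythroid genes had -0.74 (percentile 3.76, 0 higher, 1 lower, 1 of 2 alone) and ciliated genes -0.65 (percentile 2.52, at the lower bound of its range, 1 higher, 2 lower, 3 of 3 alone). The let-7 list had -0.26 (4 higher, 7 lower, 11 of 12 alone), the Dlk1-Dio3 list -0.08 (16 higher, 19 lower, 36 of 48 alone) and the miR-17-92 family 0.30 (percentile 96.2, 5 higher, 2 lower, 7 of 12 alone). Genes linked to App and Bace1 had -0.17 (3 higher, 6 lower, 9 of 12 alone) and stress genes -0.06 (1 higher, 2 lower, 3 of 6 alone). Muscle genes had 0.56 (0 of 2 differing, 1 alone), other organs -0.18 (1 higher, 1 lower, 2 of 5 alone) and the repeated genes -0.31 (2 higher, 4 lower, 7 of 9 alone). Mean and median had opposite signs in none of the lists. Signs turned under single alternatives, to -0.13 for microglia at a mean of 10 CPM or more, to 0.04 for endothelial genes with either-strand counts, and after GC correction to 0.0167 for App and Bace1 and 0.0213 for stress genes. At a mean of 10 CPM or more, values also moved to -0.79 for oligodendrocytes (2 genes left) and -1.68 for erythroid genes (1 gene left, Mir451a). Medians moved to -0.39 for neurons, -0.41 for let-7 and -0.31 for stress genes without copy-numbered genes, and to -0.057 for repeated genes after GC correction.

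Counts at genes with several copies depended on which genes were compared. Within the fixed lists, the median log2 CPM of 81 copy-numbered genes minus that of 176 single-copy genes was -8.53 in replicate 1 and -8.27 in replicate 2. The repeated genes of the Sfmbt2 type made up 43 of the 81. Without that list the difference was 0.75, so its direction depended on the repeated genes. Among all Mir genes at 1 CPM or more in either library it was 2.54. That filter leaves out genes at the floor, so it cannot speak on copies whose reads were not assigned. Over the 12 families with both kinds of gene the differences went both ways. They were -7.12 for let-7, -5.94 for miR-92, -4.09 for miR-29, -3.85 for miR-7 and -0.79 for miR-133, and 12.6 for miR-129, 10.5 for miR-219 and 0.40 for miR-19. The single-copy genes of miR-129 and miR-219 are annotated antisense to another microRNA gene and were at the floor. The other 4 families, all of the repeat list, were at 0.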

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

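The tests on GC content at 100 CPM or more, on sequence shared between hairpins, on the families with detected single-copy members and on co-transcription were chosen after the results were seen, as was the use of the GC correction as a criterion.

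Counts also stood in columns and lines outside the main measurement. Opposite-strand counts came to 265128 in replicate 1 and 272175 in replicate 2, but apart from 159 and 117 at genes without an annotated antisense partner they are the same reads that were used as sense counts at the partner gene. Among the 159 and 117, above the limit that a count of 0 allows, were counts at Mir3083 (42 and 31 counts), Mir708 (25 and 10), Mir5620 (21 and 20) and Mir34b (8 and 9). Reads mapped to several places were 44.65% and 44.69% of all reads.

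The low counts at copy-numbered genes were weighed against identical copies whose reads could not be assigned. Over the 12 families that hold both kinds of gene the median difference was 0, which decides nothing because several families were at the floor or had empty antisense genes as their single copies. In the 4 families with detected single-copy members outside the repeat list the median difference was -5.02. Families kept for detected single-copy genes tend to such a value by that choice. The values for miR-129 and miR-219 (12.6 and 10.5) decide nothing either, because their single-copy genes are antisense annotations with 0 sense counts in both libraries. Unassigned reads therefore stay open as a cause. Hairpins that share 18 bases with another gene lay at -9.66 relative to the others over all lists, and at 0.567 without the repeat list. Neither value decides, because 80 of the 81 repeat genes share sequence and without them the pooled median of sharing hairpins was not lower. That median does not speak for single families. Copies lay lower in let-7 (-7.12) and miR-92 (-5.94), and higher in miR-129 and miR-219. Shared sequence and low expression of the repeats both stay open, and the design names no biological contrast that bears on it.

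For the 241 genes that differed between the libraries, sampling noise is argued against by their share of 47.2% (30.6% to 73.4% under other low-count filters). A few abundant genes shifting the scale are argued against by TMM scaling, which moved the log2 ratios by only 0.024 and gave 0.992 times as many calls. GC content correlated with the log2 ratio at a rho of 0.176 across the tested genes, between the bounds set beforehand, and at 0.349 among the 189 genes at 100 CPM or more. With a linear trend removed there were 222 calls, but at this depth small differences are called too, so that count does not decide. Over the 308 genes at a mean of 10 CPM or more, the trend took the SD of log2 ratios from 0.666 to 0.648. Most of the spread thus lay outside a linear trend in GC content of the whole hairpin. The GC content of the reads themselves was not measured, so GC content may contribute, as in a difference of library preparation. Blood or vessel content cannot be told apart from other causes, since the erythroid median rests on 2 genes (percentile 3.76), and differences between animals, dissections and trimming were not tested.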

How the results depend on the processing

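Alternatives set beforehand left the dispersion (0.2999 to 0.3062) close to its main value. Apart from the ratio limit, they left the count of differing genes within 1.5 times its own (their share ran from 30.6% to 73.4% with the low-count filter). Single-replicate values aside, 32 recomputed values of the main results moved beyond their limit, some of them under alternatives added after seeing the data. The others stayed within it. The limit was the replicate spread for shares and the copy difference, and 1.5 times for counts. For list differences it was the SD of the random-list medians, and for the dispersion its interval over genes. The cause was not tested for any change below except where the alternative itself removes genes. A ratio of 1.5 or more as well left 94 genes, and 10 CPM left 301. With either-strand counts the top-10 share was 64.5%, list shares were 0% for oligodendrocytes, 0.334% for microglia, 0.200% for endothelial, 0.00011% for erythroid and 0.0405% for other organs, the endothelial difference was 0.0359 and the copy difference -7.03. That column leaves out antisense pairs, so 27 genes fell under 1 CPM and the oligodendrocyte and erythroid differences (2 lists) had no value. With all reads as denominator the top-10 share was 25.3%. Without Mir139 in the denominator, shares were 40.5% for let-7, 14.3% for Dlk1-Dio3, 3.66% for neurons, 1.22% for miR-17-92, 0.369% for microglia, 0.257% for choroid, 0.106% for repeats and 0.0447% for other organs. Without copy-numbered genes, shares were 1.57% for neurons and 0.161% for oligodendrocytes, and differences -0.39 for neurons, -0.41 for let-7 and -0.31 for stress genes. At a mean of 10 CPM or more the differences were -0.79 for oligodendrocytes (2 genes), -0.13 for microglia (4 genes) and -1.68 for erythroid genes (1 gene). The erythroid value was the same at 1 or more counts (3 genes). Added after seeing the data, the microglia share without Mir146 was 0.186%, the repeat difference after GC correction -0.057 (that correction also turned the App and Bace1 median to 0.0167 and the stress median to 0.0213), and the copy difference without the repeat list 0.749. The copy difference among all Mir genes at 1 CPM or more was 2.54, against the direction in the lists, but that filter leaves out genes at the floor. Each replicate alone lies within 1 SD of a mean of 2 by construction, so leaving one out says nothing about stability. The copy difference ran from -8.53 to -8.27. No paired analysis was possible because the labels give 1 group.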

Other observations

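The tests in this part were chosen after the results were seen.

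Epithelial microRNA genes outside the naming rule, chosen after their values were seen, were mostly lower in replicate 2, like Mir183. Mir182, its neighbour on chromosome 6, had 54.8 CPM in replicate 1 and 11.2 CPM in replicate 2. At another locus on that chromosome, Mir200c had 89.2 and 19.3 CPM and Mir141 11.8 and 2.24 CPM. In the cluster on chromosome 4 the members parted, with Mir429 at 160.9 and 79.7 CPM, Mir200a at 16.6 and 8.73 CPM and Mir200b at 100.1 and 163.3 CPM. Mir103-2 and Mir103-1, relatives of Mir107 elsewhere in the genome, also had lower values in replicate 2, at 46.2 and 12.99 CPM and at 5.55 and 1.12 CPM. Mir107 shares 18 bases with 2 other microRNA genes, so its fall and theirs may not be independent. Mir9-3 was higher in replicate 2, at 15.2 and 63.8 CPM, while Mir9-1 had 124.6 and 154.5 CPM. These copies share sequence, so their levels are uncertain.

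A hypothesis is that part of the difference between the libraries lies in the transcription or processing of whole clusters. Log2 ratios of genes within 10000 bases of each other on one strand had an intraclass correlation of 0.377 (0.048 to 0.575, 44 clusters, permutation p = 0.0001, the smallest that the permutations can give). At a mean of 10 CPM or more it was 0.221 (-0.17 to 0.55, permutation p = 0.0173), an interval that spans both signs. Without the Dlk1-Dio3 genes it was 0.415 (0.015 to 0.653). Picked after their values were seen, Mir183 and Mir182 moved together, with log2 ratios of -2.25 and -2.28. Other mates parted, as Mir221 and Mir222 (-0.72 and 0.25), Mir195a and Mir497 (0.95 and -0.18), and Mir34c and Mir34b (-1.49 and 0.72). Co-transcribed changes therefore stay open as a part of the difference. Cluster mates may also resemble each other in sequence and base content.

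The detected genes of the Dlk1-Dio3 cluster were not at one level (SD of log2 CPM 2.96), which restates their range and is no separate test. Between the libraries, log2 ratios in the cluster ran from -1.30 at Mir376b to 1.91 at Mir370.

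Another hypothesis was that reads unique by few bases shift between libraries. The median log2 ratio in size was 0.368 for 76 hairpins that share 18 bases with another gene and 0.325 for 229 others, a difference of 0.0438 (permutation p = 0.325), which leaves that open.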
